A study of Sus scrofa with 3 samples.

How the data were processed

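Gene expression was measured in 3 pig cell populations with 1 library each: peripheral blood mononuclear cells (PBMC), bone marrow derived mesenchymal stem cells (BM-MSC) and cells labelled as attached bone marrow cells (BMAC). Per the labels' protocols, RNA was extracted with Trizol and 500 ng of total RNA went into a Lexogen QuantSeq library. QuantSeq primes on the poly(A) tail and sequences a fragment near the 3' end of each transcript, so that counts are not scaled by transcript length here and depend on how well the annotated 3' ends match the transcripts made. The labels do not say how the cells were isolated or kept, nor which animal each population came from.

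The deposited values are raw counts per row of a gene annotation, as their whole numbers and unequal totals show. Bowtie2 and bedtools are named, without version or role, per the submitters' processing notes. The genome build, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The 3 libraries list the same 26965 rows under 26466 symbols. Rows with the same symbol were summed, which concerned 81 symbols, 45 of them transfer RNAs. All 26466 symbols are in the RefSeq table of the assembly Sscrofa11.1, which was used only for names and for which genes neighbour or overlap each other. No coordinates were taken from it, since the build behind the counts is not stated. Because strand use is unknown, a gene that overlaps another row there holding at least 25% of its count is named together with that row, and its value is uncertain.

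Counts were divided by the library total and given as counts per 1000000 (CPM). Ratios were taken as log2((CPM + 1)/(CPM + 1)) of the libraries compared. With 1 library per population there is no replicate check of any difference, no test between populations was run, and no p-value is given. Instead a gene was counted as different when its log2 ratio was at least 2 in size (4-fold after the pseudocount of 1 CPM) and the higher library held at least 10 CPM and at least 10 counts. Folds printed for a gene are ratios of CPM without pseudocount, with a 95% exact conditional (Clopper-Pearson) interval. A fold against a library with 0 counts is a lower bound computed with 3 counts in that library and is written as "at least". Counts of 3 correspond to 0.194 CPM in PBMC, 0.176 CPM in BM-MSC and 0.198 CPM in BMAC, and 10 CPM to 155, 171 and 152 counts. No molecular identifiers were used here, so intervals and bounds cover counting error only, not variation between animals, cultures or library preparations.

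The size rule, the alternatives, the rule for naming genes and 31 gene lists were fixed before the data were examined. Genes were named from the 6 genes with the largest log2 ratio in each direction among those past the size rule, leaving out LOC symbols; up to 3 members of each list with the largest ratio in size; all members of the lists of MSC surface markers and of haematopoietic markers; the 5 highest genes of each library; and, as an example of a small difference, the member of a list with the smallest ratio. Some genes that this rule takes are not reported here, and counts and medians of lists include them. The other lists were extracellular matrix, contractile and cytoskeletal, osteogenic, adipogenic, chondrogenic, haematopoietic niche and growth factor, MSC immunomodulatory, T cell, NK and cytotoxic cell, B and plasma cell, monocyte and macrophage, granulocyte and precursor, osteoclast, dendritic cell, erythroid, megakaryocyte and platelet, endothelial, MHC class II, MHC class I, inflammatory cytokine and chemokine, interferon-stimulated, proliferation, senescence-associated, immediate-early, pluripotency, lysosomal, housekeeping, ribosomal protein and mitochondrially encoded genes. Of the genes listed by name, 10 had no row under that symbol and were not analysed here. A list member was measured in a pair when at least 1 of its libraries reached 10 CPM. For lists with at least 3 measured members, the median log2 ratio is given with its percentile among 10000 random lists of the same size, matched on mean level in 20 bins. The percentile describes these libraries and is not a p-value. Where members had 0 counts in a library, a bounded median is added, computed without pseudocount and with 0 taken as 3 counts. Similarity of libraries was described by Spearman's rho across genes above the floor, without p because genes are not independent replicates. The relation of BMAC to the other libraries was described by its position on the log2 scale between PBMC and BM-MSC.

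The size rule and the random lists were checked on simulated counts with 200 genes altered by known folds. The simulation held counting noise alone, and the altered genes were taken from those well above the floor. For each of the 3 pairs, 100% of genes altered 8-fold and 0% of genes altered 2-fold passed the rule, and 0 unaltered genes did. Such values check the computation and give no error rate for real libraries, since both folds lie far from 4-fold for this noise. Intervals were checked on separate simulated counts, for genes well above the floor with the same level in both libraries. That check does not cover large folds or ratios against few counts. Under the noise they assume, the intervals held the true ratio for 95.2% of genes for BM-MSC against PBMC, 95.7% for BMAC against PBMC and 94.8% for BM-MSC against BMAC. Of 40 random lists of unaltered genes per pair, 1, 3 and 3 lay outside the middle 95%, in the same order. The alternatives fixed beforehand were TMM and upper-quartile factors from edgeR, median-of-ratios factors, pseudocounts of 0.1 and 5, floors of 1 and 50 CPM, 8-fold and 2-fold rules, thinning to the smallest total, and leaving out ribosomal protein and mitochondrially encoded genes. Added after seeing the data were leaving out 5 ribosomal RNA-like rows (RN18S, RN5-8S and 3 unnamed rows whose counts follow RN18S), leaving out all overlapping rows, and keeping rows with the same symbol apart. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, R 4.3.3 with edgeR 4.0.16 for scaling factors, and matplotlib 3.10.9.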

Results

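The data were 3 libraries of 3' end counts from pig cells, 1 each from PBMC, BM-MSC and BMAC. Total counts were 15445903 in PBMC, 17069344 in BM-MSC and 15122997 in BMAC. At least 1 count was found for 22156, 21032 and 20962 genes, and 9315, 9375 and 9529 genes reached 10 CPM. The same 5 rows were the highest in each library, RN18S and the unnamed rows LOC102158401, LOC110258214, LOC110258600 and LOC102163816. RN18S, the 18S ribosomal RNA, stood at 12700 CPM in PBMC, 37800 CPM in BM-MSC and 26600 CPM in BMAC, and the first 3 of the unnamed rows followed it closely, so it was not clear whether these rows count the same reads. RN18S, RN5-8S and those 3 rows together took 5.29% of the counts in PBMC, 15.5% in BM-MSC and 11.4% in BMAC. Mitochondrially encoded genes took 4.92%, 3.36% and 1.93%, and ribosomal protein genes 5.69%, 4.5% and 5.15%. No difference between libraries below has a replicate check, and intervals in parentheses are 95% intervals for counting error.

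BM-MSC were set against PBMC to describe how the marrow stromal population differs from blood mononuclear cells. Genes of the extracellular matrix and the contractile cytoskeleton were far higher in BM-MSC, and genes of T, B, natural killer and myeloid cells were far higher in PBMC. COL1A1 and COL1A2, the chains of type I collagen, stood at 6890 and 4800 CPM in BM-MSC against 0.129 and 0.0647 CPM in PBMC, or 53200-fold (14700 to 440000) and 74200-fold (13300 to 2.93e+06) higher. ACTA2, smooth muscle actin, was 2820-fold higher (2030 to 4020) at 6570 CPM. PTPRC, which encodes the leukocyte antigen CD45, was 2590-fold higher in PBMC (1660 to 4300), at 2880 CPM against 1.11 CPM. PEG10, an imprinted gene derived from a retrotransposon, had 0 counts in PBMC and 6160 CPM in BM-MSC, at least 31700-fold more. Of 11428 genes above the floor, 1630 were higher in BM-MSC and 1794 higher in PBMC by the 4-fold rule, 165 and 361 of them under LOC symbols.

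Matrix genes were measured for 22 list members, of which 21 were higher in BM-MSC (median log2 ratio 7.06, percentile 100 of random lists, bounded median 8.03). BGN, the proteoglycan biglycan, had 0 counts in PBMC and 1020 CPM in BM-MSC, at least 5240-fold more. The exception was TGFBI, 3.11-fold higher in PBMC (2.70 to 3.59) and so below the rule. Of 12 contractile and cytoskeletal genes, 10 were higher in BM-MSC (median 6.49, percentile 100, bounded median 6.99). CTGF, a list member that encodes a secreted protein, was at least 5440-fold higher and TAGLN 4400-fold (1720 to 16200), while CNN2 differed 1.39-fold (1.27 to 1.51). CRYAB, a small heat shock protein gene that overlaps the row C9H11orf1, was 2570-fold higher in BM-MSC (1670 to 4210).

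Surface markers used to define MSCs were mostly higher in BM-MSC, though some were shared with or higher in blood cells. Of 11 measured, 7 were higher in BM-MSC and 1 in PBMC (median 2.13, percentile 99.9, bounded median 2.17). PDGFRB was 294-fold higher (149 to 681), NT5E (CD73, overlapping LOC102157437) 22.9-fold (16.4 to 32.9), PDGFRA 22-fold (16 to 31.2), THY1 (CD90) 7.47-fold (6.93 to 8.07), CD9 4.51-fold (4.05 to 5.03), ITGB1 4.20-fold (4.05 to 4.35) and CD248 at least 73.0-fold. ENG (CD105) was 3.32-fold higher (2.59 to 4.29), below the rule. ALCAM was 8.66-fold higher in PBMC (7.91 to 9.50), and CD44 and MCAM, which overlaps CBL, were 2.98-fold (2.85 to 3.12) and 2.91-fold (2.71 to 3.13) higher there. VCAM1, NGFR and LEPR stayed below 10 CPM in both libraries. Among the haematopoietic markers that MSCs lack by definition, 4 of 5 measured were higher in PBMC (median -5.66, percentile 0, bounded median -7.12). SLA-DRA was at least 2460-fold higher and ITGAM, which overlaps LOC110259903, 82.1-fold (56.3 to 125). CD14 was 3.56-fold higher (2.67 to 4.82), and CD34 and CD79A were under 2 CPM in both libraries. CD79A stood at 0.388 CPM in PBMC although the B cell gene MS4A1 stood at 454 CPM there. Because counts depend on the annotated 3' ends, this low value need not mean that the transcript was absent.

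**Figure D1:**
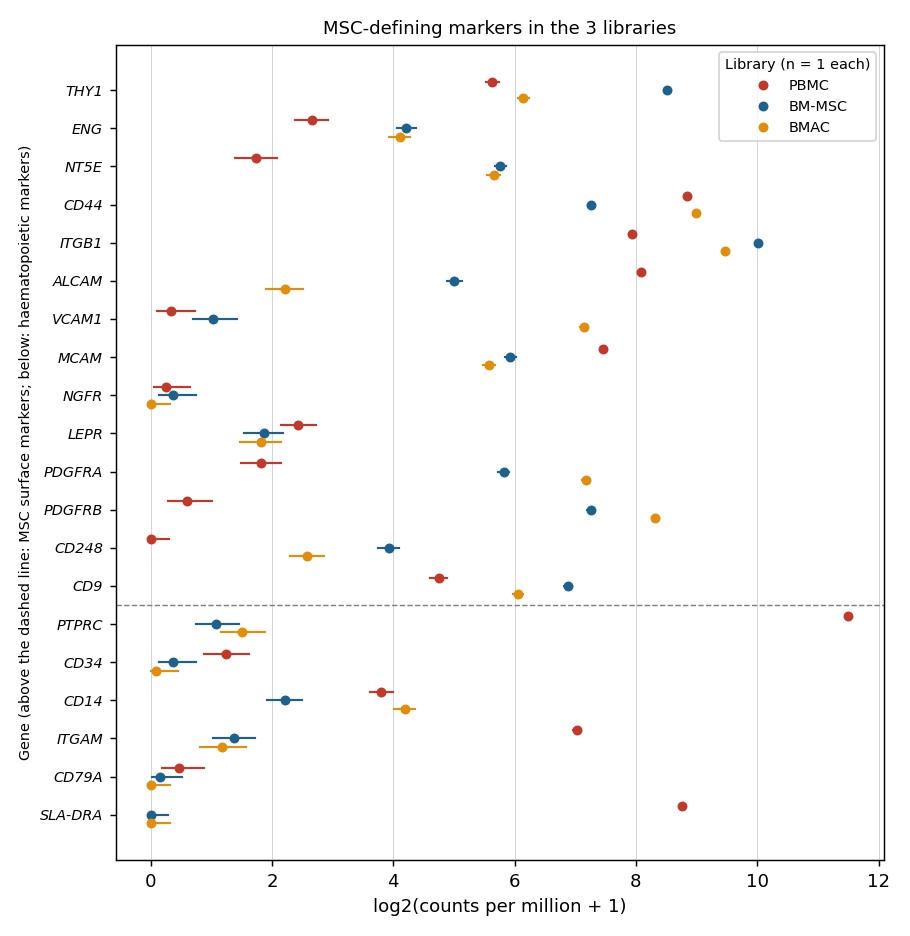
Levels of MSC surface markers (above the dashed line) and haematopoietic markers (below it) as log2(CPM + 1) in the 3 libraries, 1 point per library, with bars for the 95% Poisson interval of the count. PTPRC stands at 2880 CPM in PBMC against 1.11 CPM in BM-MSC and 1.85 CPM in BMAC, ALCAM is highest in PBMC at 270 CPM, and VCAM1 stands at 140 CPM in BMAC against 1.05 CPM in BM-MSC and 0.259 CPM in PBMC.

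Leukocyte genes formed the other side of the comparison. All measured NK, B cell and granulocyte markers, and all T cell markers but CD247, reached the floor through PBMC alone. That favours a call towards PBMC, so their counts describe these genes and are no test. All 15 measured T cell markers were higher in PBMC (median -6.65, percentile 0, bounded median -8.04). After the pseudocount the largest ratio was that of IL7R, which overlaps LOC106508147 (346 against 0.0586 CPM, 5910-fold, 1060 to 234000), and the smallest that of CD8A (23.5-fold, 13.5 to 44.8). Also higher in PBMC were 10 of 10 NK and cytotoxic markers (median -4.29, percentile 0, bounded median -7.68), such as TBX21 (441-fold, 172 to 1620), and 12 of 12 B and plasma cell markers (median -5.58, percentile 0, bounded median -7.75), such as MS4A1 (7750-fold, 1390 to 306000) and PAX5 (212-fold, 159 to 289). Of 10 MHC class II genes, 10 were higher in PBMC (median -6.14, percentile 0, bounded median -7.29), with SLA-DQA1 at least 3020-fold. MHC class I genes were lower in BM-MSC by less, 6 of 12 past the rule (median -1.91, percentile 0.1), with SLA-1 (overlapping LOC100513601) at 501 CPM against 3540 CPM. Monocyte and macrophage markers were split: 9 of 13 were higher in PBMC (median -4.65, percentile 0, bounded median -6.61), TYROBP by 97.5-fold (71.2 to 137), while LGMN and GPNMB, lysosomal genes that are not limited to myeloid cells, were 89.2-fold (73.0 to 110) and 90.5-fold (67.8 to 124) higher in BM-MSC. Dendritic cell markers were higher in PBMC for 6 of 8 (median -3.97, percentile 0, bounded median -5.40), granulocyte markers for 3 of 3 (median -3.61, percentile 15, bounded median -6.75), osteoclast markers for 3 of 4 (median -3.56, percentile 1.2) and endothelial markers for 3 of 4 (median -3.20, percentile 2.0). The exceptions past the rule were CTSK, 62.3-fold higher in BM-MSC (54.6 to 71.3), and ERG, 7.96-fold higher there (6.48 to 9.87). Outside the lists, the signalling genes LAPTM5, ARHGAP15, INPP5D and RHOH and the transcription regulator AFF3 were among the 6 largest ratios towards PBMC after the pseudocount and without LOC symbols, at 5580-fold (1910 to 27100), 812-fold (660 to 1010), 5640-fold (1560 to 46600), 10200-fold (1830 to 403000) and 690-fold (537 to 903).

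Haematopoietic niche and growth factor genes were higher for 10 of 13 and lower for 1 (median 3.20, percentile 100), with CSF1 57.4-fold (40.7 to 83.6), KITLG 77-fold (46.5 to 138) and IGF1 42.1-fold (29.2 to 63.1). The list member CXCL12 stayed below the floor in every library, at 1.17 CPM in BM-MSC, 0.595 CPM in BMAC and 0.194 CPM in PBMC. MSC immunomodulatory genes were higher for 6 of 8 (median 4.10, percentile 100), with HMOX1 103-fold (81.4 to 132) and the prostaglandin E2 enzymes PTGES 204-fold (79.3 to 750) and PTGS2, which overlaps PLA2G4A, 108-fold (58.5 to 226). Senescence-associated genes were higher for 4 of 7 and lower for 1 (median 4.33, percentile 100), with the cell cycle inhibitor CDKN1A 45.0-fold (37.8 to 54.0). The lower member was LMNB1, at 3.16 CPM against 42.4 CPM in PBMC. LMNB1 is lost in senescence, so its direction reads opposite to that of the other members in every comparison. Proliferation genes were higher in PBMC for 7 of 11 (median -2.62, percentile 0.6), with TOP2A 17.6-fold (14.5 to 21.6) and MKI67 14.0-fold (10.2 to 19.5). All measured members but TYMS reached the floor through PBMC alone, so here too the count and median are no test. Lysosomal genes were higher in BM-MSC for 4 of 14 and lower for 1 (median 1.27, percentile 99.9), with CTSL 581-fold higher (199 to 2820) and CTSS 19.9-fold higher in PBMC (17.8 to 22.2). Cytokine and chemokine genes went both ways, 3 of 8 in each direction (median 1.22, percentile 85.6, bounded median 1.37), with CCL2 at least 794-fold higher in BM-MSC and CCL5 64.5-fold higher in PBMC (46.6 to 91.8).

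Lineage genes were sparse. Of 10 osteogenic genes 3 were measured, 2 of them higher in BM-MSC (median 3.25, percentile 91.2), namely MSX2 (157-fold, 43.1 to 1300) and SPP1 (31.4-fold, 14.2 to 86.5). Chondrogenic genes were higher for 2 of 5 (median 0.747, percentile 81.8, bounded median 0.787), COL11A1, which overlaps LOC110260367, by 356-fold (258 to 506) and SOX9 by at least 69.1-fold. Among 2 measured adipogenic genes, CFD, which overlaps MED16, was at least 856-fold higher in PBMC and PLIN2 was 2.95-fold higher in BM-MSC (2.79 to 3.13). KLF4 was the 1 pluripotency factor measured, 11.1-fold higher in BM-MSC (8.41 to 14.9). Of 2 platelet markers ITGA2B was 8.13-fold higher in PBMC (5.57 to 12.2), and 0 of 8 erythroid markers reached 10 CPM. Interferon-stimulated genes had a median of 0.139 (percentile 65.9), with MX2 and IFIH1 higher in PBMC among 12. This median turned to -0.217 with a floor of 1 CPM, -1.09 with a floor of 50 CPM and -0.0109 without overlapping rows. Immediate-early genes had a median of 0.745 (percentile 89.1), with EGR1 higher in BM-MSC among 9. Housekeeping genes (median 0.540, percentile 94.6, PGK1 4.19-fold higher in BM-MSC, 3.74 to 4.71) and mitochondrially encoded genes (median -0.373, percentile 61.1, COX2 4.82-fold higher in PBMC, 4.76 to 4.89) had 1 member each past the rule, and ribosomal protein genes 0 of 80. The ribosomal protein median of -0.256 (percentile 91.3) turned to 0.0773 with TMM and 0.103 with median-of-ratios factors. Across genes Spearman's rho was 0.324, and 41.9% of genes lay within 2-fold. TMM and median-of-ratios factors moved the median of all genes from -0.161 to 0.227 and 0.258, and the share of differing genes that were higher in BM-MSC from 47.6% to 58.5% and 59.5%. IFIH1 and COX2 were below 4-fold with these factors, and CD248, CD9, SPP1, SOX9, CD8A, PRF1, TNFRSF17 (overlapping LOC100739121), S100A12, S100A8, ITGA2B, TEK (overlapping LOC102166359), IFIH1 and PGK1 with a pseudocount of 5 CPM.

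BMAC were set against PBMC in the same way. Matrix genes again led the side of the marrow cells and leukocyte genes the side of blood. In this pair 7 of 10 measured inflammatory cytokine genes were also higher in the marrow cells, and 3 were lower. COL1A2, COL1A1 and COL3A1 stood at 4120, 3220 and 3000 CPM in BMAC, 63600-fold (11400 to 2.51e+06), 24900-fold (6880 to 205000) and 46400-fold (8320 to 1.83e+06) above PBMC. IL6, an acute-phase cytokine, stood at 409 CPM against 0.0647 CPM from 1 count (6310-fold, 1130 to 249000). PTPRC was 1560-fold higher in PBMC (1080 to 2340), at 1.85 CPM in BMAC. Of 11371 genes above the floor, 1591 were higher in BMAC and 1451 higher in PBMC, 206 and 322 of them under LOC symbols.

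Of 22 matrix genes, 21 were higher in BMAC (median 7.90, percentile 100, bounded median 8.72), and TGFBI was within 1.16-fold (1.04 to 1.29). IGFBP5, an insulin-like growth factor binding protein, was 17000-fold higher (4690 to 140000), the proteoglycan FMOD 7030-fold (2400 to 34100) and the aldo-keto reductase AKR1CL1 5090-fold (2180 to 15700). Contractile and cytoskeletal genes were higher for 9 of 12 (median 4.82, percentile 100, bounded median 5.15), with CALD1 309-fold (268 to 360). MSC surface markers were higher for 4 of 11 and lower for 1 (median 1.45, percentile 99.5). PDGFRB was 615-fold higher (312 to 1430), VCAM1 541-fold (211 to 1990), PDGFRA 56.8-fold (41.4 to 80.0) and NT5E (overlapping LOC102157437) 21.1-fold (15.1 to 30.4), whereas ALCAM was 74.4-fold higher in PBMC (57.0 to 98.9). THY1 and CD44 differed 1.43-fold (1.30 to 1.58) and 1.12-fold (1.08 to 1.15), with both higher in BMAC. ENG was 3.05-fold (2.37 to 3.97), ITGB1 2.89-fold (2.78 to 3) and CD9 2.53-fold (2.25 to 2.85) higher in BMAC, MCAM (overlapping CBL) 3.74-fold higher in PBMC (3.44 to 4.06), and CD248, NGFR and LEPR were under 10 CPM in both libraries.

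Leukocyte genes were low in BMAC too, where the same markers again reached the floor through PBMC alone. T cell markers were higher in PBMC for 15 of 15 (median -6.59, percentile 0), NK and cytotoxic markers for 10 of 10 (median -4.41, percentile 0, bounded median -7.42), B and plasma cell markers for 11 of 12 (median -5.40, percentile 0, bounded median -7.19) and MHC class II genes for 10 of 10 (median -6.02, percentile 0, bounded median -7.62). LEF1 was 279-fold (204 to 393) and BANK1 438-fold (307 to 650) higher in PBMC, MS4A1 at least 2290-fold and CD74 at least 960-fold. TNFRSF17, which overlaps LOC100739121, was the B cell exception, below the rule after the pseudocount. It was 4.12-fold higher in PBMC (3.05 to 5.65). ARHGAP15, LAPTM5 and INPP5D were again among the 6 largest ratios towards PBMC, taken in the same way, at 1690-fold (1230 to 2380), 4940-fold (1690 to 24000) and 5000-fold (1380 to 41300). So were, in this pair, the integrin gene ITGA4 (2600-fold, 1010 to 9540) and ARHGDIB, which overlaps LOC110260734 (4630-fold, 1280 to 38200). Haematopoietic markers were higher in PBMC for 4 of 5 (median -5.86, percentile 0, bounded median -6.69), with SLA-DRA at least 2180-fold and ITGAM (overlapping LOC110259903) 103-fold (66 to 172). CD34 and CD79A were under 2 CPM in both libraries, and CD14 differed from the others, at 17.3 CPM in BMAC against 12.9 CPM in PBMC (1.33-fold, 1.10 to 1.61). Monocyte and macrophage markers were higher in PBMC for 9 of 13 and lower for 2 (median -4.76, percentile 0, bounded median -6.69), with TYROBP 1120-fold (384 to 5450) and LYZ at least 481-fold. Dendritic cell markers were higher in PBMC for 7 of 8 (median -4.26, percentile 0, bounded median -4.99), granulocyte markers for 3 of 3 (median -3.77, percentile 14.5, bounded median -5.99), osteoclast markers for 3 of 4 (median -3.55, percentile 1.2, bounded median -4.75) and endothelial markers for 3 of 4 (median -2.64, percentile 3.2). CTSK and ERG were again the exceptions past the rule, 15.2-fold (13.2 to 17.4) and 12.1-fold (9.92 to 15) higher in BMAC. MHC class I genes were higher in PBMC for 6 of 12 (median -1.91, percentile 0), PSMB9 by 15.4-fold (12.7 to 18.9).

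Cytokine and chemokine genes were higher in BMAC for 7 of 10 and lower for 3 (median 4.51, percentile 100, bounded median 5.11), with CCL2 at least 1840-fold and IL1A 121-fold (84.5 to 179) higher. The 3 lower genes, named after their values were seen, were IL1B (0 counts in BMAC, 216 in PBMC), CCL5 (4.43 against 140 CPM) and TNFSF13B (0.397 against 24.1 CPM). TNF, below the floor, had 0 counts in BMAC and 50 in PBMC. Niche and growth factor genes were higher for 9 of 13 and lower for 1 (median 4.10, percentile 100), with VEGFA 168-fold (113 to 262), KITLG 134-fold (81.2 to 240) and ANGPT1 55.9-fold (46.1 to 68.5). Immunomodulatory genes were higher for 5 of 7 (median 3.92, percentile 100), with PTGES 1490-fold (581 to 5460) and PTGS2 (overlapping PLA2G4A) 672-fold (365 to 1400). Senescence-associated genes were higher for 4 of 7 (median 4.60, percentile 100), and proliferation genes had 0 of 11 past the rule (median -0.184, percentile 34.6, and 0.0887 with TMM factors). Interferon-stimulated genes were higher in PBMC for 4 of 11 (median -1.66, percentile 1.3), with MX2 61.6-fold (37.1 to 110) and OAS2 7.51-fold (6.21 to 9.15). Mitochondrially encoded genes were higher in PBMC for 6 of 13 (median -1.82, percentile 0), with ND3 8.07-fold (7.90 to 8.25). Osteogenic genes were higher in BMAC for 2 of 3 (median 3.97, percentile 98.7), with SPP1 458-fold (210 to 1250), and chondrogenic genes for 3 of 4 (median 2.95, percentile 98.9, bounded median 3.32), with SOX9 at least 174-fold. Lysosomal genes were higher for 3 of 14 and lower for 1 (median 0.880, percentile 99.3), immediate-early genes for 1 and lower for 1 of 7 (median 0.236, percentile 74.0), and housekeeping genes for 2 of 10, GAPDH (overlapping IFFO1) 4.85-fold (4.70 to 5.01) and PGK1 7.41-fold (6.64 to 8.29). The housekeeping median of -0.143 (percentile 67.1) turned to 0.127 with TMM factors, and the ribosomal protein median of -0.0598 (percentile 98.7, 0 of 80 past the rule) to 0.220. Of 2 adipogenic genes CFD (overlapping MED16) was 27.1-fold higher in PBMC (21.8 to 34.1), of 2 platelet markers ITGA2B was 24.8-fold higher in PBMC (12.8 to 54.9), KLF4 was 6.30-fold higher in BMAC (4.71 to 8.56), and 0 of 8 erythroid markers were measured. Spearman's rho across genes was 0.367, and 48.8% of genes lay within 2-fold. TMM and median-of-ratios factors moved the median of all genes from -0.120 to 0.207 and 0.219, and the share of differing genes that were higher in BMAC from 52.3% to 60% and 60.3%. HAPLN1 (overlapping LOC102165705), PRF1, S100A12, S100A8, ITGA2B, TEK (overlapping LOC102166359), IFIT2 (overlapping LIPA), FOS and KLF4 were below 4-fold with a pseudocount of 5 CPM.

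Both marrow populations differed from PBMC largely in the same genes. Higher than in PBMC in both comparisons were 1150 genes, 70.6% of all 1630 of BM-MSC and 72.3% of all 1591 of BMAC. Lower in both were 1270 genes, 70.8% of 1794 and 87.5% of 1451. Opposite directions were found for 3 genes, named here after their values were seen: CYSLTR2, a leukotriene receptor gene (11.2 CPM in PBMC, 1.29 in BM-MSC and 133 in BMAC), PHYHIPL (122, 25.7 and 2500 CPM, in the same order) and LOC110256649 (83.2, 0.41 and 1520 CPM), the last of which overlaps PHYHIPL. Of the 10938 genes tested in both, 1387 were higher in BM-MSC, 1363 higher in BMAC, 1794 lower in BM-MSC and 1451 lower in BMAC, and independent lists of these sizes would share 173 and 238 genes. Unchanged libraries simulated against the same PBMC library shared 0 and 0, but they carry counting noise alone, under which no unaltered gene passed the rule, so this value gives no measure of the shared library. Part of the excess may come from the shared PBMC library, which cannot be split. For the 3424 genes past the rule between BM-MSC and PBMC, the BMAC level lay nearer to BM-MSC for 3027 (88.4%) and nearer to PBMC for 397, with a median position of 0.919 on a scale from 0 at PBMC to 1 at BM-MSC. It lay beyond BM-MSC for 1191 genes and beyond PBMC for 72.

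**Figure D2:**
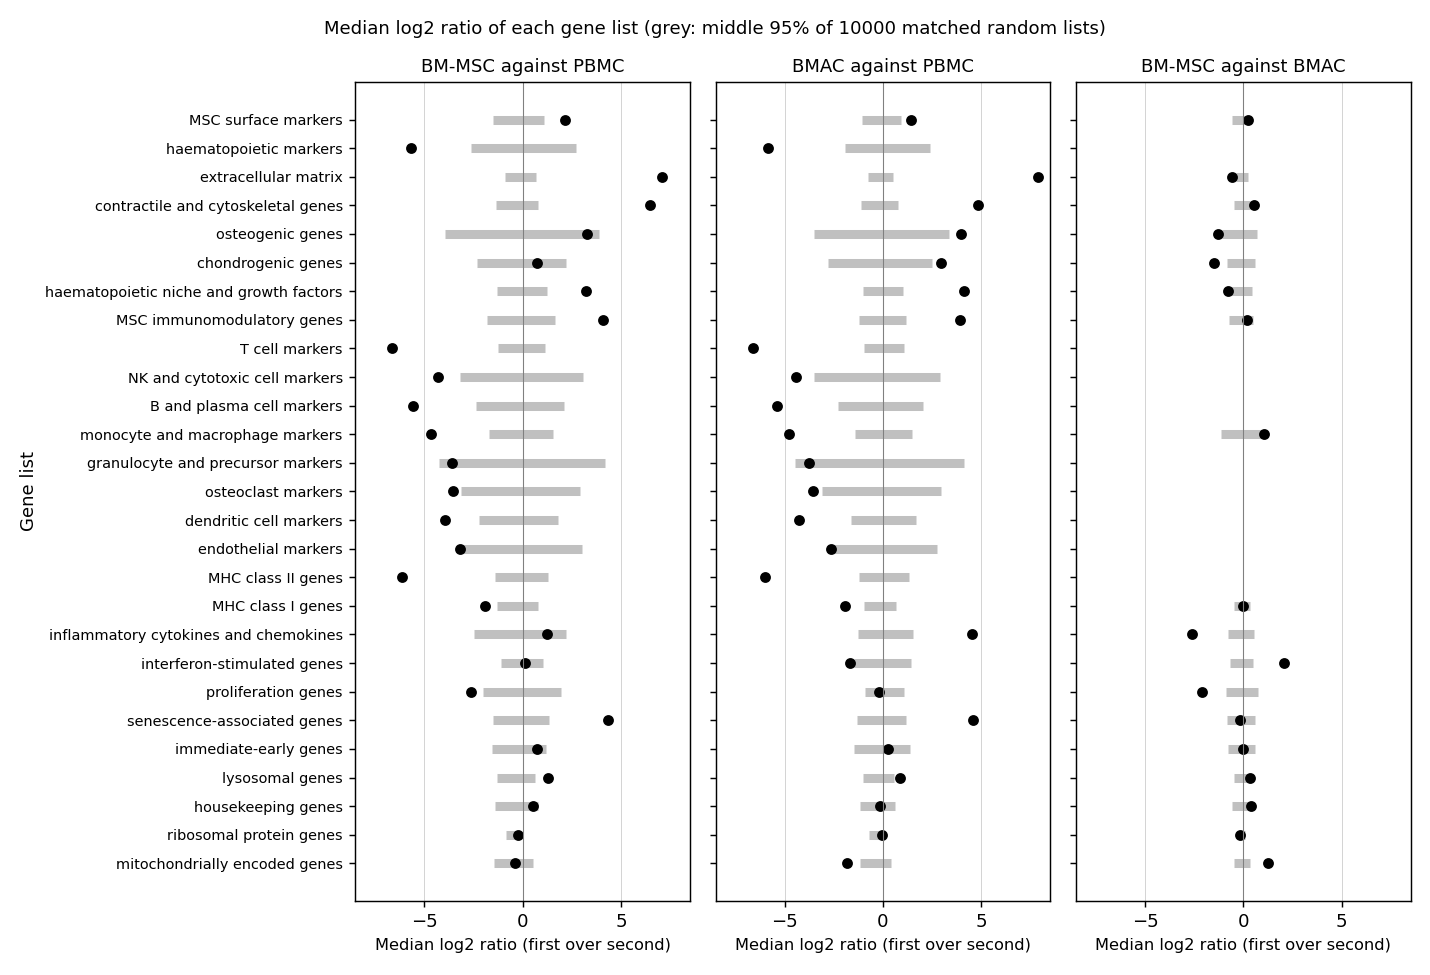
Median log2 ratio of each gene list (black point) in the 3 pairs of libraries, with the middle 95% of 10000 matched random lists in grey; lists with fewer than 3 measured members in a pair have no point. Extracellular matrix genes stand at 7.06 and 7.90 against PBMC and at -0.592 between BM-MSC and BMAC, where cytokine genes (-2.61), proliferation genes (-2.11) and interferon-stimulated genes (2.08) lie outside the grey range.

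BM-MSC were set against BMAC to describe how the marrow populations differ from each other. They were much more alike, with 80.7% of 10303 genes within 2-fold, but cytokine genes, proliferation genes and VEGFA were higher in BMAC, and the contractile genes ACTA2 and CNN1, the elastic fibre genes MFAP5 and ELN and interferon-stimulated genes were higher in BM-MSC. IL1A was 108-fold (78.4 to 154) and IL6 22-fold (19.7 to 24.7) higher in BMAC, at 235 and 409 CPM, and CXCL8, a neutrophil chemoattractant, stood at 75.5 CPM against 0.0586 CPM from 1 count (1290-fold, 231 to 51000). ACTA2 was 43.2-fold higher in BM-MSC (41.5 to 45.1), at 6570 against 152 CPM. By the 4-fold rule 299 genes were higher in BM-MSC and 331 higher in BMAC, 53 and 78 of them under LOC symbols, and Spearman's rho across genes was 0.809.

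After the pseudocount and without LOC symbols, the 6 largest ratios towards BMAC were those of TRH, the precursor of thyrotropin-releasing hormone (661 against 3.63 CPM, 182-fold, 142 to 238), the chemokine AMCF-II (1020 against 6.33 CPM, 162-fold, 134 to 197), the acute-phase gene SAA3 (718 against 4.45 CPM, 161-fold, 129 to 205), STAC (155-fold, 117 to 210), the aminopeptidase LVRN (147-fold, 104 to 215) and PHYHIPL, which overlaps LOC110256649 (97.5-fold, 88.7 to 107). TRH, AMCF-II and SAA3 were at 0.259, 0.129 and 0.129 CPM in PBMC. The 6 largest towards BM-MSC, taken in the same way, were those of IFITM3, an antiviral membrane protein gene (389 CPM against 0 counts, at least 1960-fold), the elastic fibre genes MFAP5 (743-fold, 254 to 3610) and ELN (654-fold, 223 to 3170), COL11A1, which overlaps LOC110260367 (94.2-fold, 79.6 to 112), TMEM229A (at least 280-fold) and the adhesion molecule NCAM1 (82.0-fold, 54.0 to 131).

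Cytokine and chemokine genes were higher in BMAC for 4 of 7 (median -2.61, percentile 0), and CCL2 differed 2.32-fold (2.21 to 2.43) in the same direction. At the same time the leukocyte gene PTPRC was at 1.85 CPM in BMAC and 1.11 CPM in BM-MSC, 1.66-fold (0.896 to 3.15), a difference not detectable at this depth. Niche and growth factor genes were higher in BMAC for 4 of 13 and lower for 2 (median -0.793, percentile 0.5), with VEGFA 18.1-fold (15.9 to 20.7) and LIF 16.6-fold (11.5 to 24.7) higher and IGF1 10.1-fold (8.39 to 12.3) higher in BM-MSC. Immunomodulatory genes went both ways (3 of 8 higher in BMAC, 1 in BM-MSC, median 0.178, percentile 83.8), with PTGES 7.30-fold (6.81 to 7.84) and PTGS2 (overlapping PLA2G4A) 6.22-fold (5.85 to 6.62) higher in BMAC and TNFAIP6 10.9-fold (7.66 to 16.1) higher in BM-MSC. That median was -0.833 without overlapping rows and -0.974 with a floor of 50 CPM. Proliferation genes were higher in BMAC for 6 of 9 (median -2.11, percentile 0), with RRM2 14.6-fold (11.1 to 19.5), MKI67 12.3-fold (8.96 to 17.2) and TOP2A 9.83-fold (8.03 to 12.1). All measured members but TYMS (52.1 CPM in BMAC, 24.9 CPM in BM-MSC) reached the floor through BMAC alone. That favours a call towards BMAC, so the count and median describe these genes and are no test. Interferon-stimulated genes were higher in BM-MSC for 5 of 10 (median 2.08, percentile 100), with OAS2 14.6-fold (12.2 to 17.7) and IFIT3 and IFIT2, both overlapping LIPA, 7.15-fold (5.23 to 9.97) and 8.22-fold (5.28 to 13.4), while IFIH1 differed 1.23-fold (0.996 to 1.52). IFIT2 and IFIT3 were under 4-fold with a pseudocount of 5 CPM. The 5 interferon-stimulated genes past the rule reached the floor through BM-MSC alone. That favours a call towards BM-MSC, so their count describes these genes and is no test.

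Contractile and cytoskeletal genes were higher in BM-MSC for 2 of 12 (median 0.540, percentile 99.9), ACTA2 and CNN1 (12.9-fold, 11.1 to 15), and TPM1 was within 1.01-fold (0.989 to 1.03). Matrix genes were higher in BMAC for 2 of 22 (median -0.592, percentile 0.1), TNC 5.04-fold (4.82 to 5.26) and COL6A3 5.02-fold (4.79 to 5.26). MSC surface markers were higher in BM-MSC for 2 of 12 and in BMAC for 1 (median 0.235, percentile 92.5). VCAM1 was 133-fold higher in BMAC (83.9 to 225), and ALCAM and THY1 were 8.59-fold (6.50 to 11.5) and 5.22-fold (4.89 to 5.57) higher in BM-MSC. CD44, PDGFRA and PDGFRB were 3.33-fold (3.18 to 3.48), 2.57-fold (2.38 to 2.78) and 2.10-fold (2 to 2.20) higher in BMAC. CD248, CD9, ITGB1 and MCAM (overlapping CBL) were 2.86-fold (2.20 to 3.76), 1.78-fold (1.65 to 1.93), 1.45-fold (1.42 to 1.49) and 1.28-fold (1.17 to 1.42) higher in BM-MSC, and differences in NT5E (overlapping LOC102157437, 1.08-fold, 0.983 to 1.2), ENG (1.09-fold, 0.916 to 1.29) and LEPR (1.05-fold, 0.666 to 1.66) were not detectable at this depth. CD14, the 1 haematopoietic marker above the floor, was 4.75-fold higher in BMAC (3.59 to 6.37), just below the rule after the pseudocount. SLA-DRA had 0 counts in both libraries, ITGAM (overlapping LOC110259903), CD34 and CD79A were under 2 CPM, and the surface marker NGFR was under 1 CPM. Chondrogenic genes were higher in BMAC for 2 of 6 and lower for 1 (median -1.50, percentile 0.1). The 2 were HAPLN1, which overlaps LOC102165705 (13.7-fold, 9.19 to 21.3), and SOX6 (4.27-fold, 3.84 to 4.76), both below 4-fold with a pseudocount of 5 CPM, and SOX6 also with median-of-ratios and upper-quartile factors. Osteogenic genes were higher in BMAC for 1 of 3 (median -1.30, percentile 1.3), with SPP1 14.6-fold higher (12.7 to 16.9). The osteogenic median was 0.254 without overlapping rows, a setting that leaves out RUNX2, overlapping SUPT3H, and brings DLX5 above the floor with the smaller totals.

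Mitochondrially encoded genes had a median of 1.27 (percentile 100) with 0 of 13 past the rule, ND4 being 3.20-fold higher in BM-MSC (3.16 to 3.25) and COX1 within 1.04-fold. Lysosomal genes (median 0.360, percentile 98.9, 0 of 14) and housekeeping genes (median 0.414, percentile 98.5, 0 of 10) leaned to BM-MSC. Ribosomal protein genes had a median of -0.167 (percentile 8.1, 0 of 80). Senescence-associated genes were higher in BMAC for 2 of 7 and in BM-MSC for 1 (median -0.172, percentile 38.2), IGFBP5 being 6.95-fold higher in BMAC (6.75 to 7.15). LMNB1, the other member higher there, is lost in senescence, so its higher level does not point the way the list is named. It was below 4-fold with a pseudocount of 5 CPM and under all 3 scaling factors. The list median turned to 0.734 with a floor of 50 CPM. The MHC class I median of -0.00233 (percentile 63.5) turned to 0.190 with TMM factors, and 1 of 11 members was past the rule, SLA-3, which overlaps SLA-2. The immediate-early median of -0.00478 (percentile 60.2) turned to 0.0479, with FOS alone of 9 past the rule, 5.80-fold higher in BM-MSC (3.91 to 8.90) and under 4-fold with a pseudocount of 5 CPM. Monocyte and macrophage markers had 4 measured members (median 1.04, percentile 98.0), with GPNMB 9.95-fold higher in BM-MSC (8.99 to 11). CTSK, the 1 osteoclast marker measured, and CD86, 1 of 2 dendritic cell markers, were 4.11-fold (3.96 to 4.27) and 14.1-fold (11.6 to 17.3) higher in BM-MSC. The adipogenic gene PLIN2, the T cell gene CD247, the platelet gene GP9 (overlapping RAB43), the MHC class II regulator CIITA, the pluripotency factor KLF4 and the endothelial genes PECAM1 and ERG were the measured members of their lists and lay within 2-fold. NK, B cell, granulocyte and erythroid markers had 0 measured members.

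**Figure D3:**
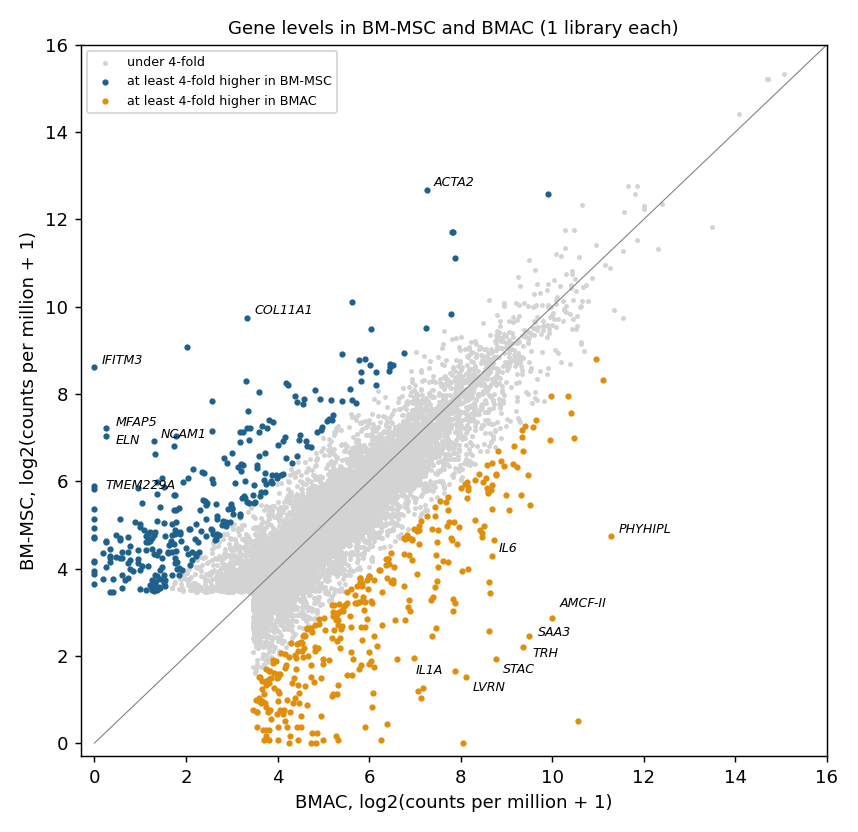
Level of each of the 10303 genes above the floor in BMAC (horizontal axis) and BM-MSC (vertical axis), as log2(CPM + 1), 1 point per gene and 1 library per axis, with the line of equal levels. The 299 genes higher in BM-MSC by the 4-fold rule are blue and the 331 higher in BMAC orange, with ACTA2 at 6570 against 152 CPM and IL6 at 18.6 against 409 CPM among the labelled genes.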

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

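The 3 alternatives added after seeing the data were leaving out ribosomal RNA-like rows, leaving out overlapping rows and keeping rows with the same symbol apart, and all others were fixed beforehand. No paired analysis was possible because each population has 1 library, and for the same reason no library could be left out. Of 225 log2 ratios of named genes of at least 2 in size, 0 turned direction under the 3 scalings and 2 pseudocounts. That 0 was fixed beforehand and shows no robustness. A pseudocount cannot turn a ratio, and scaling factors between 0.906 and 1.16 are too close to turn one of this size. Of the 225, 31 dropped below 4-fold under at least 1 of these settings, 30 of them with a pseudocount of 5, which by construction shrinks ratios of low genes. With median-of-ratios factors IFIH1 (-1.90) and COX2 (-1.91) for BM-MSC against PBMC and SOX6 (-1.99) and LMNB1 (-1.98) for BM-MSC against BMAC were among these. Of 52 list medians outside the middle 95% of random lists, 2 turned direction. The ribosomal protein median of BMAC against PBMC became 0.22 with TMM factors, 0.23 with median-of-ratios factors and 0.036 without ribosomal RNA-like rows, and the osteogenic median of BM-MSC against BMAC became 0.254 without overlapping rows, where RUNX2 (overlapping SUPT3H) is left out and DLX5 passes the floor because the totals are smaller. The numbers of genes at least 4-fold different stayed within 1.5 times under every scaling, with a pseudocount of 0.1, a floor of 1 CPM, thinning and all sets of genes left out. With a pseudocount of 5, 176 genes were higher in BM-MSC than in BMAC and 198 lower. A floor of 50 CPM, which leaves fewer genes, gave 856 genes higher in BM-MSC than in PBMC and 1056 lower, 907 higher in BMAC than in PBMC and 811 lower, and 122 higher in BM-MSC than in BMAC and 176 lower. In the same order an 8-fold rule gave 975 and 942, 977 and 899, and 141 and 133, and a 2-fold rule 3014 and 3629, 2817 and 3002, and 845 and 1140. The share of genes with BMAC nearer to BM-MSC was 87.3% with a floor of 1 CPM, 91.0% with 50 CPM, 90.6% with the 8-fold rule and 82.7% with the 2-fold rule. Rank correlations depended most on the floor: for BM-MSC with PBMC, BMAC with PBMC and BM-MSC with BMAC they were 0.608, 0.624 and 0.898 at 1 CPM and -0.0478, 0.0258 and 0.62 at 50 CPM. They were 0.34, 0.38 and 0.818 without ribosomal RNA-like rows and 0.383, 0.418 and 0.829 without overlapping rows. Apart from these construction effects, the cause was not tested. Depth limits genes near 10 CPM, which rest on 152 to 171 counts, and ratios against 0 to 3 counts, whose upper bounds are wide or open.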

Other observations

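The tests of the EIF1AY pattern, the leukocyte and scaling tests of the cytokine pattern, the depth, interferon and IFITM row tests of IFITM3 and the list of HOX genes were chosen only after the result was seen. The hypoxia and NF-kB lists were chosen after genes such as VEGFA and IL6 had been seen to be higher in BMAC, but their members were fixed before their own values were seen, and genes already seen were left out.

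HOX genes are transcription factors of positional identity along the body axis. Of 36 HOX genes 8 were measured in each comparison with PBMC, and 8 of 8 were higher in BM-MSC (median log2 ratio 3.85, bounded median 6.02) and 8 of 8 in BMAC (median 4.73, bounded median 6.90). These members reached the floor through the marrow library, and the list was picked after its values were seen, so the counts describe these genes and test nothing. Below the floor HOXB2 (15 counts in PBMC, 0 in BM-MSC and BMAC) and HOXB3 (overlapping LOC106505099, 20, 9 and 0 counts) went the other way. Between the marrow populations 0 of 9 were past the 4-fold rule, with a median of -1.19. HOXC6 (overlapping LOC110260669) was at 17.2 CPM in BM-MSC and 65.7 CPM in BMAC, 3.83-fold (3.36 to 4.37), and HOXC8 (overlapping LOC106510294) at 13.5 and 44.0 CPM, 3.27-fold (2.81 to 3.81). HOXB7 went the other way, 4.09-fold higher in BM-MSC (2.88 to 5.94) without the pseudocount. Below the floor members lay on both sides (overlapping rows not given). HOXC11 (101 counts in BM-MSC, 10 in BMAC) and HOXD9 (100 and 19) were among those higher in BM-MSC, and HOXA6 (56 and 88) among those higher in BMAC. The median therefore does not describe the whole family.

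BMAC may hold more transcripts of 2 further programmes than BM-MSC, the response to low oxygen and the targets of the inflammatory transcription factor NF-kB, which was tested as a hypothesis with lists of other genes. The median of 20 hypoxia-responsive genes was -1.01 for BM-MSC against BMAC, at percentile 0 of 10000 random lists, with 5 past the 4-fold rule, all higher in BMAC. They included the mitophagy receptor BNIP3, 6.76-fold (6.39 to 7.16), the oxygen sensor EGLN3, 11.8-fold (7.57 to 19.1), and the glycolytic enzyme HK2, 5.89-fold (5.02 to 6.95), while ADM and SLC2A1 (overlapping ZNF691) were within 1.19-fold. The median of 12 NF-kB targets was -1.56, also at percentile 0, with 3 past the rule: IL11, 15.9-fold (13.7 to 18.6), NFKBIA, 6.82-fold (6.21 to 7.5), and IER3, 4.38-fold (4.19 to 4.57). ICAM1 was within 1.04-fold and NFKBIZ within 1.03-fold. Against PBMC the hypoxia median was 0.659 (percentile 97.3) for BM-MSC and 1.48 (percentile 100) for BMAC, and the NF-kB median -0.137 (percentile 54.8) and 1.38 (percentile 99.7). By the 4-fold rule 3 hypoxia genes were higher in BM-MSC and 5 higher in PBMC, so that median hides members going the other way. For BMAC the numbers were 9 and 0. Among NF-kB targets they were 3 and 3 for BM-MSC, and 5 and 1 for BMAC. With 1 library per population these results describe the libraries and leave culture, handling and animal as open as the population.

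EIF1AY, a Y-linked translation factor gene, had 393 counts in BMAC against 9 in PBMC and 3 in BM-MSC. Reads of its X-linked copy EIF1AX are argued against, since EIF1AY counts per EIF1AX count were 40.7 times as many in BMAC as in the higher of the other libraries. Scaling cancels in this ratio and is argued against by the same value. Of the 14 rows of the files among the 10 genes on each side of EIF1AY in the RefSeq table, 10 were detected and 9 of these were at least 4-fold higher in BMAC than in both other libraries, with sums of 577 CPM in BMAC, 15.1 CPM in PBMC and 8.03 CPM in BM-MSC. This is consistent with male cells in BMAC and few or none in the other libraries, as a hypothesis, in which case BMAC and BM-MSC came from different animals, which the labels do not give, so a difference between BMAC and the other populations may also be one between animals.

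Cytokine and chemokine genes were higher in BMAC than in BM-MSC, with 4 of 7 measured list members past the 4-fold rule. PBMC-like leukocytes left among the cells are argued against by leukocyte genes: PTPRC in BMAC was 0.0642% of its PBMC level, LAPTM5 0.0202% and CORO1A had 0 counts. An admixture of the PTPRC size would bring at most 0.00512% of the BMAC level of any raised member. That value decides nothing, because every raised member was far lower in PBMC, CXCL2 the least so (6.6 against 82.8 CPM). It also does not cover leukocytes in which these cytokine genes were raised. CD14 went the other way, at 133% of its PBMC level in BMAC (17.3 against 12.9 CPM) and 28.1% in BM-MSC, but the monocyte genes TYROBP and CSF1R were at 0.089% and 0.296% in BMAC and FCER1G had 0 counts. Scaling moves all genes alike and is argued against, since the list median less that of all genes was -2.52, at percentile 0 of matched random lists. Animal and population cannot be told apart with 1 library per population, and a population difference stays open as untested, beside activation during handling, which was not analysed here.

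IFITM3 had 0 counts in BMAC, 2463 in PBMC and 6637 in BM-MSC. Depth is argued against, since 2412 counts (2.41e+03) would be due in BMAC at the lower of the other levels. Lower interferon-stimulated expression in BMAC stays open: without pseudocount the bound on the log2 ratio of IFITM3 was 10.9, the list median 2.18 and the list's highest value 3.87 (OAS2), but IFITM3 was picked for the size of its ratio, so this gap decides nothing. Reads counted at another row under an IFITM symbol are argued against by the sum of the 4 IFITM rows, which in BMAC was 3.67% of that in BM-MSC. The sum does not cover reads counted at unnamed LOC rows or left out because they map to several places. Within that sum IFITM1 went the other way, at 14 CPM in BMAC against 3.69 CPM in BM-MSC. A sequence difference of the animal at the 3' end of the gene could give 0 counts and cannot be told apart from absent expression, since 0 sequence reads were used.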
